A study of Homo sapiens with 10 samples.

How the data were processed

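RNA abundance was measured by mRNA sequencing in 10 libraries of HCT116, an established human colorectal carcinoma cell line. Per the labels, RNA was extracted with TRIzol, 150 ng of total RNA went into each library and libraries were made with a TruSeq mRNA kit. The libraries fall into 5 groups of 2. In the inhibitor experiment, cells received DMSO or the DOT1L inhibitor EPZ-5676 at 10 µM for 72 h. In the knockdown experiment, CDK9 was knocked down by shRNA and the cells are labelled EV, WT (wild-type CDK9 put back) or K56A (CDK9 with lysine 56 changed to alanine put back). The labels do not expand EV, and it is kept as a name here.

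The authors deposited 3 tables of 4 libraries each, holding FPKM per transcript (fragments per kilobase of transcript, scaled to the total of the library). One table holds DMSO and EPZ, one holds EV and WT, and one holds EV and K56A. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, STAR 2.7.1a, RSEM 1.3.3 and DESeq2 1.32.0, with genome build GRCh38, and no roles are stated there. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Per the file headers, the authors' log2 fold changes, p-values and adjusted p-values per transcript came from edgeR in the inhibitor table and from DESeq2 in the knockdown tables. Those columns were used only to describe the authors' calls. Another 4 columns of summary values per group were left unused. The tables list only transcripts above 0 in at least 2 of their 4 libraries, 62929 for the inhibitor, 72555 for WT and 74761 for K56A.

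Transcript FPKM were summed per gene as listed in the deposited tables, which pair gene IDs with symbols and coordinates. Of the 18034 gene IDs, 17972 were also found in the GENCODE list of names at hand. Each EV library stands in both knockdown tables, and its values differ by 1 constant factor (1.0007 for EV replicate 1 and 1.0006 for EV replicate 2). The K56A libraries were therefore multiplied by the mean of these factors and set beside EV and WT. For the 6 knockdown libraries, only the 69086 transcripts present in both tables were summed. Another 5675 transcripts stand only in the K56A table and 3469 only in the WT table. A gene was left out when more than 5% of its FPKM lay in transcripts listed in only 1 table, which removed 2284 of 13850 genes. That limit was set after seeing that CD83 appeared to differ between lines when one of its transcripts, listed in a single table, was missing from the sum. Values of different experiments were never tested against each other.

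The planned test depended on the unit, and for FPKM it was limma. Genes with FPKM of at least 1 in at least 2 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 (R 4.3.3), with an intensity trend, group means as the only terms and two-sided p-values adjusted by Benjamini-Hochberg at 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates changes of genes with low values. EPZ versus DMSO used its 4 libraries (13130 genes). WT versus EV, K56A versus EV and K56A versus WT came from 1 fit of the 6 knockdown libraries (11566 genes). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

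Named genes follow a rule fixed before the data were examined. CDK9 and DOT1L come first. Then come, per comparison, the 10 largest rises and 10 largest falls among genes that passed, whose groups did not overlap and whose mean FPKM was at least 2. Where fewer than 5 passed in a direction, the 5 smallest p-values in that direction are given. For each list described, up to 4 members with the smallest adjusted p are named, and members of the P-TEFb list are given whether or not they passed. Values of some list members are not reported here. Examples of transcripts in the authors' tables, the copies SMIM11A and SLX1A, and the genes FOS and CCN1 in WT versus EV, MYC, NEAT1 and XRCC6 were picked after their values were seen. A total of 33 gene lists were fixed in the same way. They cover CDK9 and DOT1L complexes, HOX genes, DNA repair, p53 targets, immediate early genes, the cell cycle, histones, interferon and NF-kB targets, metabolism and stress, colon and epithelial identity, apoptosis, ribosomal and mitochondrial genes, RNA quality and markers of other cell types. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison.

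The depth of the libraries is unknown, because the tables hold no counts. Ratios of low FPKM values between libraries repeat, as whole reads would give, and the commonest ratio puts the libraries of the inhibitor table at 1 to 1.29 times the depth of DMSO replicate 1 and the knockdown libraries at 0.868 to 1.21 times the depth of EV replicate 1. The ratios rest on few pairs (283 of 11563 for EPZ replicate 2), so they are rough. Data were simulated with the spread of these libraries, with 50 genes changed at each of 1.25-, 1.5-, 2- and 4-fold in 1 set. There the test of EPZ versus DMSO made 74 calls. It found 44 of 50 genes changed 4-fold, 27 of 50 changed 2-fold and 2 of 50 changed 1.5-fold. The test of K56A versus WT found 50, 46 and 28 of 50 at these folds and 12 of 50 changed 1.25-fold, with 10 false calls among 146. The adjusted threshold is stricter when fewer genes change, so these counts overstate what the tests can find in that case.

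The alternatives for genes were other pseudocounts, filters and scalings, the replicate number as a block, all 10 libraries or only the compared groups in a fit, and leaving out each library. Added after seeing the data were tests of transcripts, of lists without single libraries and at pseudocounts 0.1 and 1, of genes behind EPZ calls as sets in K56A versus WT (adjusted over 4 sets), of overlaps with simulated shared controls, sums over all transcripts of 1 table, no limit on transcripts listed in 1 table, and removal of trends with GC content and length. GC content and length came from GENCODE transcript sequences of the same build, for the most abundant transcript of a gene that has a sequence there, and covered 99.3% of genes of the inhibitor fit and 99.2% of the knockdown fit. The fallback to a transcript with a sequence was added when CCN1 lacked a value.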

Results

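The data address how transcript levels in HCT116 colorectal carcinoma cells respond to inhibition of DOT1L, the histone H3 methyltransferase, and to changes in CDK9, the kinase of the elongation factor P-TEFb, which releases paused RNA polymerase II. The title of the series places both in the repair of DNA double-strand breaks. Each of the 5 groups (DMSO, EPZ, EV, WT and K56A) had 2 libraries. The number of transcripts above 0 was 54216 in DMSO replicate 1, 59913 in DMSO replicate 2, and 59440 and 59403 in the EPZ libraries. Over the genes tested, log2 values of the DMSO replicates had r = 0.981, across genes, against 0.990 for EPZ (DMSO replicate 2 had r = 0.991 and 0.990 with the EPZ libraries), 0.992 for EV, 0.993 for WT and 0.994 for K56A. Genes encoded in the mitochondrial genome made up 17.3% and 17.6% of all FPKM in DMSO, 18.4% and 19.3% in EPZ, 27.9% and 27.5% in EV, 27.7% and 27.1% in WT, and 25.3% and 25.4% in K56A.

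The manipulated genes were examined first. CDK9 (ENSG00000136807, chromosome 9, 127786034 to 127790792, GRCh38) stood at 40.7 ± 4.47 FPKM (SD, n = 2) in DMSO and 40.2 ± 2.43 (n = 2) in EPZ. That is a log2 fold change of -0.02 ± 0.13 (SE, adjusted p = 0.980). In the knockdown lines it was 17.9 ± 2.19 in EV, 3018 ± 59.8 in WT and 2556 ± 78.3 in K56A (n = 2 each). Summed over transcripts, CDK9 rose 165-fold in WT and 139-fold in K56A over EV. The limma adjusted p-values were 7.6e-10 and 9.9e-10, past the threshold in all 15 alternatives. Its coding transcript rose by a smaller factor, from 11.56 and 10.96 FPKM in EV to 751 and 811 in WT. In K56A the coding transcript stood at 752 and 750. Processed transcripts made up most of the sum in WT and K56A but not in EV. DOT1L (ENSG00000104885, chromosome 19, 2163933 to 2232578) stood at 12.6 ± 0.0298 FPKM in DMSO and 10.5 ± 0.219 in EPZ, a log2 fold change of -0.25 ± 0.13 (SE) that did not pass (adjusted p = 0.756). In the knockdown lines DOT1L was much higher and differed between the lines, at 333 ± 13.1 FPKM in EV, 573 ± 6.88 in WT and 718 ± 21.4 in K56A (n = 2 each). DOT1L rose by 0.78 ± 0.04 on the log2 scale from EV to WT (adjusted p = 0.000166, past in all 15 alternatives) and by 0.32 ± 0.04 from WT to K56A (adjusted p = 0.0397, past in 6 of 14 alternatives). With GC and length trends removed, the latter became 0.20 ± 0.03 and did not pass, as its fold shrank (adjusted p = 0.0871, and 0.0109 to 0.562 over the alternatives), and the value for DOT1L with EPZ became -0.09 ± 0.12. The levels of the inhibitor and knockdown libraries come from tables normalized separately and were not tested against each other. Every comparison between the CDK9 lines is therefore also a comparison between lines with different DOT1L levels.

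**Figure D1:**
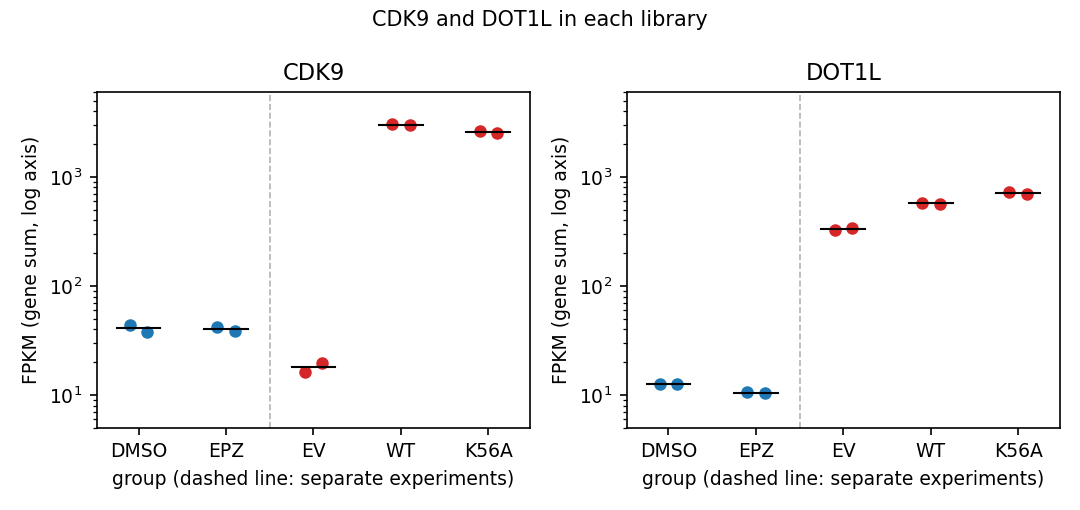
FPKM of CDK9 (left) and DOT1L (right), summed over transcripts, on a log axis, with 1 point per library and a bar at the mean of 2 libraries, for the inhibitor experiment (blue) and the knockdown experiment (red). CDK9 stands at 17.9 in EV and 3018 in WT, and DOT1L stands at 12.6 in DMSO and 333 to 718 in the knockdown lines.

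The first comparison asked which transcripts respond to 72 h of DOT1L inhibition. With EPZ, 1 of 13130 genes fell and 0 rose with limma. An unadjusted p under 0.05 was found for 765 genes, where unchanged genes alone would give a share of about 0.05. These 765 genes can therefore not be read as a set that responds. The gene that fell, SMIM11B (ENSG00000273590), encodes a small membrane protein and was listed at 0 in both EPZ libraries against 6.10 ± 2.24 FPKM (SD, n = 2) in DMSO (adjusted p = 0.0307). SMIM11B has a near-identical copy, SMIM11A, which was listed at 0 and 2.20 FPKM in DMSO and at 7.06 and 8.51 in EPZ. Summed over both copies, the libraries held 4.52 and 9.89 FPKM in DMSO and 7.06 and 8.51 in EPZ, so the call is uncertain.

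Among genes that did not pass, the smallest p-values for higher levels with EPZ belonged to SPP1, SLX1B, H2AC6, KRTAP2-3 and H2AW. SPP1, which encodes the secreted protein osteopontin, was 6.21 ± 0.383 FPKM against 2.56 ± 0.177 (SD, n = 2 each), a log2 fold change of 1.13 ± 0.17 (SE) with adjusted p = 0.756. The histone genes H2AC6 and H2AW had log2 fold changes of 1.20 ± 0.21 and 0.97 ± 0.19, and the hair keratin-associated gene KRTAP2-3 had 1.19 ± 0.22 (adjusted p = 0.756 each). SLX1B, a subunit of a structure-specific nuclease, had 1.13 ± 0.19 (adjusted p = 0.756), and its copy SLX1A held 49.0 and 40.1 FPKM in DMSO and 35.1 and 36.0 in EPZ, so reads may have been split between them. The smallest p-values for lower levels after SMIM11B belonged to TNFRSF6B, a decoy receptor for FAS ligand (-1.20 ± 0.19), the AP-1 subunit FOSL1 (-0.67 ± 0.13), the hyaluronan synthase HAS3 (-0.59 ± 0.11) and the transcription factor KLF2 (-0.58 ± 0.11), each with adjusted p = 0.756. Over the alternatives, SMIM11B passed in 5 of 8 (adjusted p from 3.4e-19 to 0.0603), TNFRSF6B in 5 of 12 and SPP1 in 3 of 11.

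Of the 30 lists tested in this comparison, 4 passed camera at the preset correlation. Of 12 measured replication-dependent histone genes, 0 passed over all genes and 4 rose when adjusted over the list alone. The median log2 fold change was 0.45 (camera adjusted p = 3.0e-05). That call was lost, with adjusted p = 0.619 with an estimated correlation. The 4 were H2AC6, H2BC4 (1.25 ± 0.34), H4C14 (0.86 ± 0.25) and H2BC5 (0.58 ± 0.18). Most transcripts of such genes lack poly(A) tails, so libraries made from mRNA capture only part of them. Of 36 interferon-stimulated genes, 0 passed over all genes and 0 when adjusted over the list alone. In all, 29 lay above 0 and the median was 0.20 (adjusted p = 2.9e-05, and adjusted p = 0.937 with an estimated correlation). BST2, which tethers budding viruses, had 0.61 ± 0.14, IFI44 had 1.25 ± 0.32, IFI6 had 0.29 ± 0.10 and SAMD9 had 0.64 ± 0.23. Of 46 DNA replication and E2F target genes, 0 passed over all genes and 0 when adjusted over the list alone. Here 38 lay below 0 and the median was -0.12 (adjusted p = 4.6e-05, and adjusted p = 0.619 with an estimated correlation). The subunits of the replicative helicase MCM5 (-0.54 ± 0.14), MCM4 (-0.29 ± 0.11) and MCM2 (-0.35 ± 0.14) and the ubiquitin ligase adaptor DTL (-0.40 ± 0.16) had its smallest p-values. Of 13 mitochondrially encoded genes, 0 passed over all genes and 0 when adjusted over the list alone. Of them 12 lay above 0 and the median was 0.10 (adjusted p = 0.00112, and adjusted p = 0.937 with an estimated correlation). MT-ATP8 had 0.59 ± 0.16, MT-ND3 0.31 ± 0.10, MT-ND4L 0.24 ± 0.11 and MT-CO3 0.12 ± 0.07. The nuclear-retained RNAs and RNA quality genes had 5 of 6 members above 0 and a median of 0.11, with TUG1 at 0.29 ± 0.12 and NORAD at 0.28 ± 0.12, and did not pass (adjusted p = 0.275). A difference in RNA quality or capture is therefore not excluded for the histone and mitochondrial lists. Without DMSO replicate 2, the lists of histones, E2F targets and mitochondrially encoded genes no longer passed, with medians of 0.44, -0.09 and 0.08 (adjusted p = 0.0945, 0.128 and 0.0945). The median of the interferon-stimulated genes was 0.11 without DMSO replicate 1, 0.30 without DMSO replicate 2 and 0.13 without EPZ replicate 2. Over 10 alternatives the adjusted p-values of these lists ran from 2.0e-12 to 0.619, from 6.6e-07 to 0.619 and from 1.3e-05 to 0.937, and those of the interferon-stimulated genes from 1.2e-05 to 0.937.

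The counts of changed genes depended on single libraries. Without DMSO replicate 1, 80 genes passed, without DMSO replicate 2 1560, without EPZ replicate 1 36 and without EPZ replicate 2 34, each with the lone library assumed to vary like the other group. Groups did not overlap for 4915 of 13130 genes (37.4%, where chance gives 33.3%).

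In the authors' deposited table of EPZ versus DMSO, 752 of 62929 transcripts of 663 genes passed, 402 higher and 350 lower. Of these, 651 (86.6%) were at 0 in both libraries of a group. Examples were a transcript of RPLP0, a ribosomal stalk protein gene, listed at 22.1 and 71.6 FPKM in DMSO and 0 in both EPZ libraries, and one of MAPKAP1, a subunit of the kinase complex mTORC2, listed at 0 in both DMSO libraries and at 6.74 and 8.42 in EPZ. NDUFA10, a respiratory complex I subunit, had a transcript at 15.7 and 12.4 FPKM in DMSO and 0 in EPZ, and another at 0 in DMSO and 9.41 and 12.4 in EPZ. These 651 transcripts belong to 586 genes, of which 569 were tested as genes, and the gene sums had a median absolute log2 fold change of 0.14, equal to the 0.14 of genes with no such call. Counting transcripts at 0 in both libraries of one pair and at a mean of at least 1 FPKM in the other gave 545 with the labels and 561 and 517 for the mislabelled splits of the same 4 libraries.

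The next comparison set cells with wild-type CDK9 put back against EV. CDK9 stood at 3018 FPKM in WT, against 17.9 in EV and 40.7 in the DMSO cells of the other experiment. That is far above the DMSO level, though these tables were normalized separately. No line without the knockdown is included, so the comparison does not show a return to the usual CDK9 level. In WT versus EV, 9 genes rose and 53 fell of 11566 tested. After CDK9 and DOT1L, the largest rise among named genes with a mean above 5 FPKM was that of DUSP5, a nuclear phosphatase of ERK, from 38.6 ± 0.235 to 55.3 ± 0.461 FPKM (SD, n = 2 each; log2 fold change 0.51 ± 0.04 SE, adjusted p = 0.00992). The MAPK pathway genes TRIB1 (0.29 ± 0.04, adjusted p = 0.0263) and ERRFI1, an inhibitor of the EGF receptor (0.26 ± 0.03, adjusted p = 0.0308), also rose. So did GRAMD1C (0.71 ± 0.11), which encodes a sterol transporter, RPS3A (0.20 ± 0.03), a ribosomal protein, and RN7SKP173 (1.00 ± 0.14), a 7SK pseudogene that may share reads with other 7SK copies and is uncertain. The AP-1 subunit FOSB fell from 110.2 ± 1.95 to 79.6 ± 1.97 FPKM (-0.47 ± 0.04, adjusted p = 0.0108) and the MAPK phosphatase DUSP1 from 18.3 ± 0.340 to 12.7 ± 1.03 (-0.51 ± 0.08, adjusted p = 0.0453). FOS, its AP-1 relative, had -0.26 ± 0.04 (adjusted p = 0.0352), and CCN1, a secreted matrix protein, 0.07 ± 0.04 (adjusted p = 0.532).

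Other falls were these. The small GTPase RAB4B, which recycles endosomes, had -0.58 ± 0.09, CYB561D2, a cytochrome b561 family member, -0.55 ± 0.07, the secreted protease KLK6 -0.43 ± 0.05, the vesicle protein SCAMP2 -0.41 ± 0.05, the tetraspanin TSPAN4 -0.41 ± 0.06, the tight junction protein CLDN7 -0.41 ± 0.04, the complex I subunit NDUFC2 -0.41 ± 0.06 and TECR, which extends very long fatty acids, -0.40 ± 0.05. Their adjusted p-values ran from 0.0125 (CLDN7) to 0.0477 (RAB4B).

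Of the 29 lists tested, 6 passed. Of 77 cytosolic ribosomal protein genes, 1 (RPS3A) rose over all genes and 47 rose when adjusted over the list alone. In all 73 lay above 0 and the median was 0.11 (camera adjusted p = 6.2e-27, and adjusted p = 0.560 with an estimated correlation). RPL7 (0.16 ± 0.03), RPS18 (0.19 ± 0.03) and RPL31 (0.15 ± 0.03) came next. Of 26 hypoxia and glycolysis genes, 0 passed over all genes and 6 fell when adjusted over the list alone. The median was -0.09 (adjusted p = 1.6e-07, and adjusted p = 0.560 with an estimated correlation). They were led by the glucose transporter SLC2A1 (-0.26 ± 0.04), the oxidoreductase ERO1A (-0.28 ± 0.05) and the glycolytic enzymes ENO1 (-0.15 ± 0.03) and ALDOA (-0.14 ± 0.03). Of 29 cholesterol synthesis and SREBP targets, 0 passed over all genes and 4 fell when adjusted over the list alone, among them SCD (-0.18 ± 0.03), EBP (-0.27 ± 0.06) and TM7SF2 (-0.32 ± 0.07). The list had a median of -0.10 (adjusted p = 0.00122, and adjusted p = 0.560 with an estimated correlation), and adjusted p = 0.0504 without WT replicate 1. That median was -0.07 without EV replicate 1 or WT replicate 1 and -0.06 without WT replicate 2. Of 7 epithelial identity genes, CLDN7 alone fell over all genes and 4 fell when adjusted over the list alone, the others being EPCAM (-0.14 ± 0.04), CLDN4 (-0.15 ± 0.04) and KRT8 (-0.12 ± 0.03). The list's median was -0.12 (adjusted p = 0.00202, and adjusted p = 0.560 with an estimated correlation).

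Of 33 genes of the unfolded protein response and of ATF4, 1 fell over all genes, the amino acid transporter SLC7A5 (-0.33 ± 0.04), and 8 fell when adjusted over the list alone. Among these were MANF (-0.20 ± 0.04), PDIA6 (-0.15 ± 0.03) and SHMT2 (-0.19 ± 0.04). The list's median was -0.07 (adjusted p = 0.00889, and adjusted p = 0.560 with an estimated correlation), and it no longer passed without EV replicate 2 (median -0.03, adjusted p = 0.134) or WT replicate 1 (median -0.06, adjusted p = 0.166). Of 17 epithelial-mesenchymal transition genes, 0 passed over all genes, and 1 rose (CCN2, 0.31 ± 0.06) and 1 fell (TIMP1, -0.24 ± 0.05) when adjusted over the list alone. TGFB2 had -0.60 ± 0.19 and TGFB1 -0.22 ± 0.07. This list had a median of -0.09 (adjusted p = 0.00582, and adjusted p = 0.560 with an estimated correlation) and did not pass without EV replicate 2 (median -0.08, adjusted p = 0.134) or WT replicate 1 (median -0.08, adjusted p = 0.0523). Without EV replicate 1 its median was -0.14. Over 10 alternatives the lowest adjusted p was 0.00034 for SREBP targets, 0.00198 for the unfolded protein response and 0.00367 for the transition genes, and the highest was 0.560 for each. Of 24 measured genes of P-TEFb and its regulators, CDK9 alone rose, over all genes and when adjusted over the list alone. The cyclin CCNT1 had 0.06 ± 0.09, the inhibitor HEXIM1 0.08 ± 0.06 and the elongation factor SUPT5H -0.04 ± 0.04, and none of these passed.

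Without EV replicate 1, 7 genes passed in WT versus EV, without EV replicate 2 2, and without WT replicate 1 or 2 3 each. Of the 18 named genes that passed, CDK9, DOT1L, DUSP5 and CLDN7 kept their calls without EV replicate 1, and CDK9 and DOT1L alone without each of the other 3 libraries. Groups did not overlap for 5033 of 11566 genes (43.5%, where chance gives 33.3%). In the authors' deposited table of the same comparison, 2419 transcripts passed, 1135 higher and 1284 lower, of which 1212 (50.1%) were at 0 in both libraries of a group.

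K56A cells were set against EV in the same way. In K56A versus EV, 22 genes rose and 69 fell of 11566 tested, and the split was 15 higher and 94 lower with each library rescaled by its median ratio. The immediate early genes FOS and FOSB, which encode AP-1 subunits, fell to 0.527 and 0.555 of their EV level. FOS (ENSG00000170345, chromosome 14, 75278826 to 75282230) went from 433 ± 0.365 to 228 ± 10.5 FPKM (SD, n = 2 each; -0.92 ± 0.04 SE, adjusted p = 2.9e-05, past in all 14 alternatives) and FOSB (ENSG00000125740) from 110.2 ± 1.95 to 61.0 ± 1.01 (-0.85 ± 0.04, adjusted p = 0.000106). DUSP1 fell from 18.3 ± 0.340 to 9.31 ± 0.491 FPKM (-0.94 ± 0.08, adjusted p = 0.00428), and HES1, a transcriptional repressor downstream of Notch, from 43.2 ± 2.24 to 30.1 ± 0.221 (-0.51 ± 0.05, adjusted p = 0.0113). Among the rises after CDK9 and DOT1L were the interferon-stimulated genes IFI27, from 18.7 ± 2.69 to 34.5 ± 2.77 FPKM (0.87 ± 0.11, adjusted p = 0.0180), IFI6 (0.37 ± 0.06, adjusted p = 0.0388) and the ubiquitin-like modifier ISG15 (0.37 ± 0.06, adjusted p = 0.0363).

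Other rises were those of GADD45A, a stress-induced growth arrest gene (0.48 ± 0.07), AMH, anti-Müllerian hormone, which lies downstream of DOT1L on the same strand (0.43 ± 0.05), ID1, an inhibitor of basic helix-loop-helix factors (0.39 ± 0.05), GH1, growth hormone (0.45 ± 0.07), and NPIPB2 (0.55 ± 0.09). NPIPB2 belongs to a family of near-identical copies and is uncertain. Other falls were those of RAB4B (-0.56 ± 0.09), the complement inhibitor CD59 (-0.52 ± 0.06), the Golgi transport gene GOLT1B (-0.51 ± 0.08), the prostaglandin E synthase PTGES (-0.48 ± 0.08), the cargo receptor subunit MCFD2 (-0.47 ± 0.05) and the endoplasmic reticulum protein TMEM33 (-0.43 ± 0.07). Adjusted p-values of these genes ran from 0.0113 (MCFD2) to 0.0459 (TMEM33). AMH had 0.28 ± 0.05 with GC and length trends removed, and GH1 had 0.41 ± 0.08 and no longer passed (adjusted p = 0.0601). Over the alternatives, GH1 passed in 5 of 14, NPIPB2 in 6 of 14, GADD45A in 7 of 15, ID1 in 9 of 15 and AMH in 10 of 15.

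**Figure D2:**
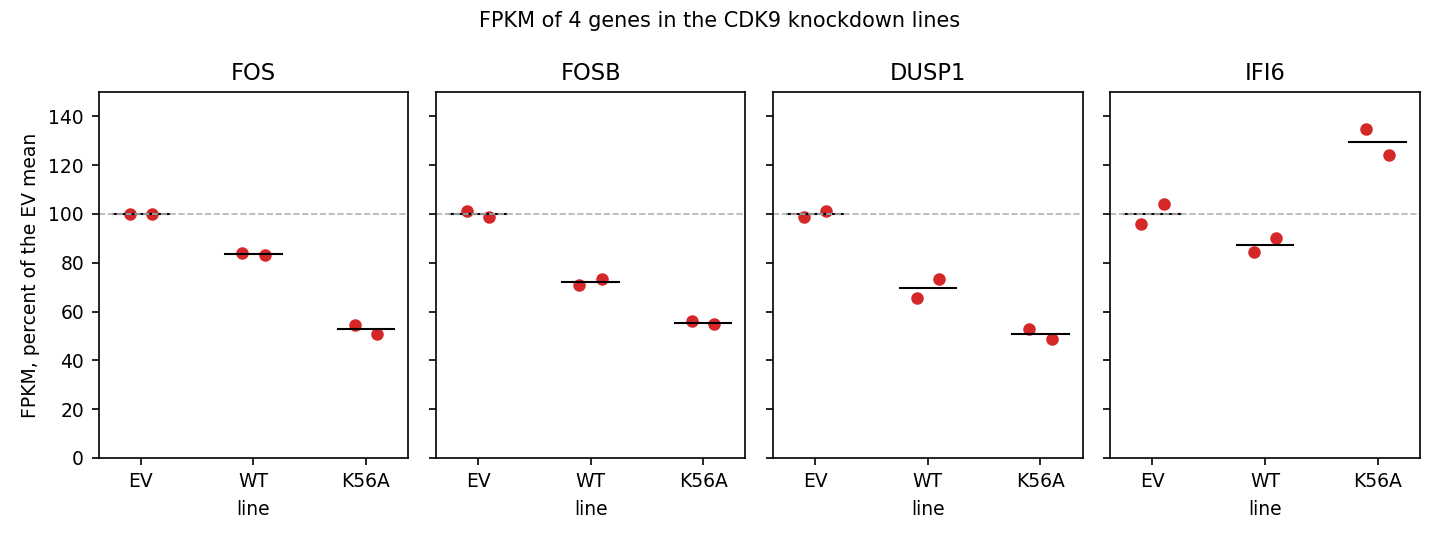
FPKM of FOS, FOSB, DUSP1 and IFI6 as a percent of the EV mean, with 1 point per library and a bar at the mean of 2 libraries, in the 3 knockdown lines. FOS, FOSB and DUSP1 are lower in WT than in EV and lower again in K56A, where FOS has 228 FPKM against 433 in EV, while IFI6 is highest in K56A.

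Of the 29 lists, 8 passed in K56A versus EV. Of 13 mitochondrially encoded genes, 7 fell over all genes and 12 fell when adjusted over the list alone. The median was -0.17 (camera adjusted p = 1.2e-18, and adjusted p = 0.226 with an estimated correlation). MT-ND5 (-0.37 ± 0.03), MT-ND2 (-0.24 ± 0.02), MT-ATP6 (-0.22 ± 0.02) and MT-CO3 (-0.16 ± 0.02) had the smallest adjusted p-values. The share of mitochondrial FPKM was 25.3% and 25.4% in K56A against 27.9% and 27.5% in EV. NEAT1, of the RNA quality genes, rose in the same comparison (given below), though its list did not pass. A difference in RNA quality or capture is therefore not excluded for the mitochondrial list. Of 26 hypoxia and glycolysis genes, 1 (ENO1, -0.20 ± 0.03) fell over all genes and 10 fell when adjusted over the list alone. PGK1 had -0.19 ± 0.03, ERO1A -0.26 ± 0.05 and LDHA -0.20 ± 0.05 (list median -0.10, adjusted p = 3.7e-09, and adjusted p = 0.330 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 0 passed over all genes and 0 when adjusted over the list alone. In all 70 lay above 0, with RPS18 at 0.15 ± 0.03 and RPL13 at 0.13 ± 0.03 (median 0.06, adjusted p = 1.9e-07, and adjusted p = 0.609 with an estimated correlation). Of 29 cholesterol synthesis and SREBP targets, 1 fell over all genes, the desaturase SCD (-0.20 ± 0.03), and 4 fell and 1 rose when adjusted over the list alone. INSIG1 had -0.36 ± 0.08 and FASN 0.20 ± 0.04 (list median -0.13, adjusted p = 8.0e-05, and adjusted p = 0.226 with an estimated correlation). The SREBP median was -0.08 without EV replicate 1 and -0.06 without EV replicate 2, and that of ribosomal proteins was 0.03 without EV replicate 1.

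Of 26 interferon-stimulated genes, 3 rose (IFI27, ISG15 and IFI6) and 1 fell over all genes, the MHC class I light chain B2M (-0.37 ± 0.04), and 5 rose and 1 fell when adjusted over the list alone. The median was 0.14 (adjusted p = 0.000877, and adjusted p = 0.433 with an estimated correlation). Of 35 immediate early and short-lived transcripts, 3 rose and 7 fell over all genes, and 5 rose and 10 fell when adjusted over the list alone. Their median was -0.04 (adjusted p = 0.0155, and adjusted p = 0.609 with an estimated correlation). DUSP5, NR4A1 and CCN1 had 0.37 ± 0.04, -0.37 ± 0.05 and -0.30 ± 0.04. The list did not pass without EV replicate 2 (median -0.02, adjusted p = 0.0552) or K56A replicate 2 (median 0.01, adjusted p = 0.133), and its median was -0.08 without K56A replicate 1. Of 11 NF-kB targets, 0 passed over all genes and 4 rose when adjusted over the list alone, namely RELB (0.49 ± 0.12), TRAF1 (1.12 ± 0.32), NFKBIA (0.20 ± 0.06) and BIRC3 (0.38 ± 0.12). Its median was 0.15, and its adjusted p = 0.0431 became adjusted p = 0.433 with an estimated correlation. Without EV replicate 1, EV replicate 2 or K56A replicate 1 the median was 0.20, 0.21 or 0.12 (adjusted p = 0.0516, 0.0552 and 0.256). Of 35 nuclear oxidative phosphorylation genes, 0 passed over all genes, and 1 rose (COX5B, 0.23 ± 0.06) and 4 fell when adjusted over the list alone, among them UQCRC1 (-0.20 ± 0.04), NDUFA9 (-0.32 ± 0.08) and SDHC (-0.19 ± 0.05). That list's median was -0.04, and its adjusted p = 0.0466 became adjusted p = 0.609 with an estimated correlation. The median was -0.01 without EV replicate 2 (adjusted p = 0.685) and -0.03 without K56A replicate 1 (adjusted p = 0.0976) or K56A replicate 2 (adjusted p = 0.0994). Over 10 alternatives the lowest adjusted p was 0.00133 for immediate early genes, 0.0231 for NF-kB targets and 0.00555 for oxidative phosphorylation.

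Without EV replicate 1, 38 genes passed in K56A versus EV, without EV replicate 2 30, without K56A replicate 1 8 and without K56A replicate 2 6. CDK9, DOT1L, FOS and FOSB kept their calls without each of the 4 libraries, and DUSP1 lost its call without K56A replicate 2. Of the 20 named genes that passed, 9, 8, 6 and 5 kept their calls in that order of libraries. IFI27 and AMH kept theirs without EV replicate 1 and none of the others, HES1 and MCFD2 without either EV library, TMEM33 without EV replicate 2, CD59 without K56A replicate 1 and ID1 without K56A replicate 2. Groups did not overlap for 5270 of 11566 genes (45.6%, where chance gives 33.3%). In the authors' deposited table of the same comparison, 2841 transcripts passed, 1413 higher and 1428 lower, of which 1248 (43.9%) were at 0 in both libraries of a group.

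Both lines with CDK9 put back were compared with the same EV libraries, and their log2 fold changes had r = 0.627 across 11566 genes, or 0.570 without CDK9 and DOT1L. Unchanged groups simulated against shared controls gave r = 0.498 (0.462 to 0.545 over 100 simulations). The simulated genes varied independently of each other. That range therefore leaves out deviations that many genes of an EV library share, and does not bound what shared controls can give. The covariance was 0.0170 without CDK9 and DOT1L, against 0.00823 simulated, a difference of 0.00881. Of the genes that rose, the 9 and the 22 shared 4, namely CDK9, DOT1L, DUSP5 and TRIB1. Without CDK9 and DOT1L, 2 were shared between 7 and 20, where independent lists would share 0.0121. Of those that fell, 24 were shared between the 53 and the 69, where independent lists would share 0.316. Independent lists leave out the shared controls, so unchanged groups were again simulated against shared EV libraries (100 simulations). Their 7 and 20 smallest p-values for higher levels shared 1.65 genes on average (0 to 4), and their 53 and 69 for lower levels shared 10.3 (4 to 21). The controls could not be split with 2 libraries on each side, so part of the excess may come from the shared controls.

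The direct contrast of the mutant asked which genes differ between cells with K56A and with WT CDK9. It joins 2 tables that were normalized separately, tied by the constant factors of the EV libraries. In K56A versus WT, 2 genes rose and 5 fell of 11566 tested. IFI6 (ENSG00000126709), an interferon-induced mitochondrial protein gene, rose from 114 ± 5.27 to 168 ± 9.94 FPKM (SD, n = 2 each; 0.56 ± 0.06 SE, adjusted p = 0.0329), and DOT1L rose as given above. FOS fell from 362 ± 1.61 to 228 ± 10.5 FPKM (-0.67 ± 0.04, adjusted p = 0.00117), FOSB from 79.6 ± 1.97 to 61.0 ± 1.01 (-0.38 ± 0.04, adjusted p = 0.0329) and CCN1 (ENSG00000142871), a secreted matrix protein and target of YAP, from 183 ± 0.965 to 142 ± 6.07 (-0.36 ± 0.04, adjusted p = 0.0329). The mitochondrially encoded genes MT-ND5 (-0.25 ± 0.03) and MT-ATP6 (-0.23 ± 0.02) fell, each with adjusted p = 0.0297. FOS passed in all 13 alternatives (adjusted p from 9.6e-05 to 0.0254), FOSB in 7 of 13 (0.0109 to 0.372), CCN1 in 7 of 14 (0.0109 to 0.610), IFI6 in 7 of 14 (0.00863 to 0.343) and the mitochondrial genes in 8 of 14 each. FOS and FOSB were not among the genes of the fit of all 10 libraries. Tests of transcripts are not among these alternatives. Of 47461 transcripts tested in K56A versus WT, 2 were called higher and 0 lower, so no transcript of FOS, FOSB or CCN1 was called lower. CDK9 itself, summed over transcripts, had -0.24 ± 0.07 and did not pass (adjusted p = 0.220, past in 1 of 14 alternatives). Its coding transcript stood at 751 and 811 FPKM in WT and at 752 and 750 in K56A. Processed transcripts stood at 1152 and 1134 in WT against 802 and 775 in K56A, at 497 and 430 against 388 and 345, and at 660 and 601 against 667 and 629.

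Genes with the next smallest p-values for higher levels were AMH (0.42 ± 0.05, adjusted p = 0.0533), the helicase RECQL4 (0.29 ± 0.04, adjusted p = 0.0568) and CHTF18, part of a sliding clamp loader (0.32 ± 0.04, adjusted p = 0.0568), and they did not pass. With GC and length trends removed, AMH had 0.20 ± 0.05, RECQL4 0.12 ± 0.04 and CHTF18 0.13 ± 0.05. They passed in 2 of 14, 2 of 13 and 1 of 13 alternatives, with adjusted p from 0.0131 to 0.997, from 0.0183 to 0.516 and from 0.0183 to 0.549. Of 24 genes of P-TEFb and its regulators, 0 passed over all genes and 0 when adjusted over the list alone, with CCNT1 at -0.22 ± 0.09, the elongation factor ELL at 0.23 ± 0.08, HEXIM1 at 0.09 ± 0.06 and SUPT5H at 0.10 ± 0.04.

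Of the 29 lists, 4 passed in K56A versus WT. Of 13 mitochondrially encoded genes, 2 fell over all genes and 11 fell when adjusted over the list alone. All 13 lay below 0, with a median of -0.15 and MT-ND2 and MT-CO3 at -0.16 ± 0.02 and -0.14 ± 0.02 (camera adjusted p = 2.4e-17, and adjusted p = 0.343 with an estimated correlation). The mitochondrial share of FPKM was 27.7% and 27.1% in WT against 25.3% and 25.4% in K56A. Of 77 cytosolic ribosomal protein genes, 0 passed over all genes and 8 fell when adjusted over the list alone, led by RPS3A (-0.16 ± 0.03), RPL21 (-0.16 ± 0.03), RPL35A (-0.14 ± 0.03) and RPL31 (-0.13 ± 0.03). Their median was -0.05 (adjusted p = 1.4e-10, and adjusted p = 0.767 with an estimated correlation). Of 26 interferon-stimulated genes, 1 rose over all genes, and 6 rose and 1 fell when adjusted over the list alone. Of them 23 lay above 0 and the median was 0.17 (adjusted p = 1.4e-06, and adjusted p = 0.439 with an estimated correlation). HLA-C had 0.27 ± 0.03, ISG15 0.33 ± 0.06 and IFI27 0.59 ± 0.11, and none of these passed over all genes. Of 35 immediate early and short-lived transcripts, 3 fell over all genes, and 4 rose and 13 fell when adjusted over the list alone. Their median was -0.07 (adjusted p = 7.9e-06, and adjusted p = 0.645 with an estimated correlation) and -0.10 without K56A replicate 1. Members next to pass were NR4A1 (-0.33 ± 0.05), HES1 (-0.37 ± 0.05), DUSP1 (-0.43 ± 0.08) and EGR2 (-0.34 ± 0.08).

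**Figure D3:**
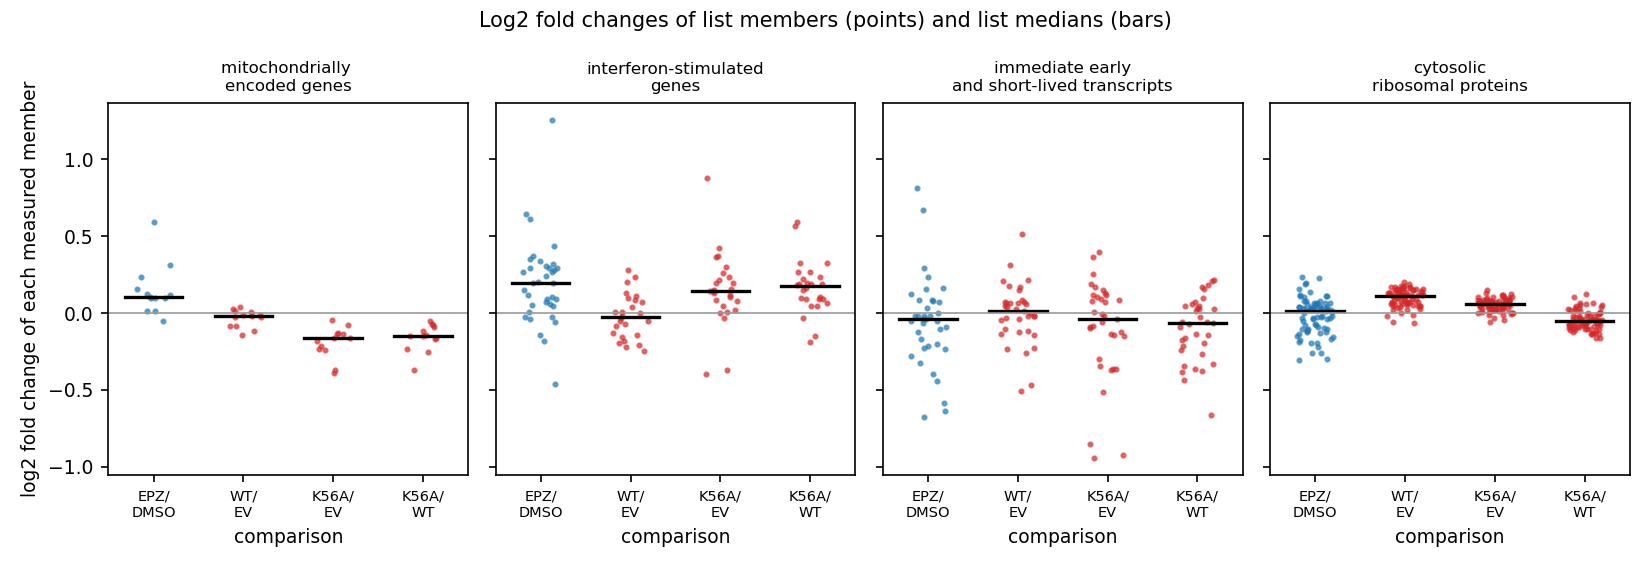
Log2 fold changes of the measured members of 4 lists in the 4 comparisons (points, 1 per gene) with the list median as a bar, in blue for the inhibitor experiment and red for the knockdown lines. The 13 mitochondrially encoded genes have a median of -0.15 in K56A versus WT and 0.10 in EPZ versus DMSO, and cytosolic ribosomal proteins have medians of 0.11 in WT versus EV and -0.05 in K56A versus WT.

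Without WT replicate 1 or 2, 2 genes passed in K56A versus WT, and without K56A replicate 1 or 2 only 1, and FOS was the 1 of the 7 called genes that kept its call without each of these 4 libraries. Groups did not overlap for 5254 of 11566 genes (45.4%, where chance gives 33.3%).

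Genes of DNA double-strand break repair were a question of their own, given the title of the series. Of the measured homologous recombination genes (42 in the inhibitor experiment and 31 in the knockdown lines), 0 passed in any comparison over all genes or when adjusted over the list alone. The list medians were -0.03 with EPZ, 0.03 in WT versus EV, 0.07 in K56A versus EV and 0.02 in K56A versus WT. In K56A versus WT, the recombination genes RAD54L, ABRAXAS1 and MUS81 had 0.33 ± 0.11, -0.23 ± 0.08 and 0.18 ± 0.06. Of 13 non-homologous end joining genes, 0 passed over all genes in K56A versus WT and 2 rose when adjusted over the list alone, the polymerase POLL (0.32 ± 0.07) and the Ku-binding PAXX (0.22 ± 0.05). Against EV, 0 passed over all genes and 1 fell when adjusted over the list alone in each line, POLL in WT (-0.31 ± 0.07) and the Ku subunit XRCC6 in K56A (-0.16 ± 0.04). Of 34 genes of double-strand break signalling, 0 passed over all genes and 0 when adjusted over the list alone, with KAT5 at 0.20 ± 0.05, CLSPN at -0.17 ± 0.07 and USP28 at 0.21 ± 0.09. Of 10 mismatch repair genes, 0 passed over all genes and 2 rose when adjusted over the list alone, LIG1 (0.24 ± 0.05) and POLD1 (0.22 ± 0.06). The lowest camera adjusted p over the 4 comparisons was 0.430 for homologous recombination, 0.433 for end joining, 0.433 for break signalling, 0.472 for Fanconi anaemia genes, 0.628 for mismatch repair and 0.420 for base and nucleotide excision repair. No list was tested with GC and length trends removed, so the rises of these repair genes are not freed of such trends. Removing them in K56A versus WT took RECQL4 from 0.29 to 0.12 and CHTF18 from 0.32 to 0.13, and IFI6 from 0.56 to 0.54. Transcript levels say nothing of the repair itself, which was not measured in these files.

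The other lists that passed camera in no comparison had lowest adjusted p-values of 0.117 (P-TEFb and its regulators), 0.340 (DOT1L and its partners), 0.287 (HOX and MEIS genes), 0.199 (p53 targets), 0.370 (G2 and mitosis), 0.262 (heat shock genes), 0.262 (Wnt and beta-catenin targets), 0.271 (intestinal differentiation, 3 measured members), 0.787 (apoptosis regulators), 0.247 (nuclear-retained RNAs and RNA quality) and 0.999 (fibroblast markers, 3 members, tested with EPZ alone). Single members that rose in K56A versus EV were GADD45A among the p53 targets, MYC (0.26 ± 0.04) among the Wnt targets and NEAT1 (0.21 ± 0.03) among the RNA quality genes. HOX and MEIS genes, known to depend on DOT1L in leukaemia, included HOXD8 (0.61 ± 0.16), MEIS2 (-0.59 ± 0.16), HOXB4 (-0.54 ± 0.17) and HOXA3 (-0.48 ± 0.16) with EPZ, and 0 of the 25 measured passed over all genes or when adjusted over the list alone. Markers of blood, endothelium and nerve cells had 1, 0 and 2 measured members in the inhibitor experiment and 0, 0 and 1 in the knockdown lines, too few to test.

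The last comparison set the response to EPZ beside the difference of K56A from WT, which share no libraries. Log2 fold changes of 10641 genes had r = -0.196 and rho = -0.270 across genes, which are not independent replicates. A mislabelled split of the inhibitor libraries against the labelled K56A split gave an absolute r of 0.276, above the labelled value, and leaving out single libraries moved r from -0.0635 (without DMSO replicate 1) to -0.267 (without EPZ replicate 1). Without EPZ replicate 2 it was -0.0839. Of the genes behind the authors' EPZ calls, 231 with a raised transcript had a median of 0.01 in K56A versus WT (fry adjusted p = 0.299) and 221 with a lowered one a median of 0.02 (fry adjusted p = 0.0772). Neither set passed camera at the preset correlation (adjusted p = 0.862 and 0.307). The 151 tested among the 200 genes with the smallest p for higher levels with EPZ had a median of -0.01 (fry adjusted p = 0.572, camera adjusted p = 0.191). The 160 for lower levels with EPZ had a median of 0.07 (fry adjusted p = 0.126) and passed camera towards higher levels in K56A (adjusted p = 0.0193, and adjusted p = 0.432 with an estimated correlation). Leaving out single libraries moved that adjusted p from 1.2e-07 (without EPZ replicate 1) to 0.862 (without EPZ replicate 2). It was 0.688 without DMSO replicate 1, 0.0732 without WT replicate 1 and 0.291 without K56A replicate 1. The median of that set was 0.12 without EPZ replicate 1, 0.11 without K56A replicate 2, 0.10 without DMSO replicate 2 and 0.04 without EPZ replicate 2 or K56A replicate 1. The set for higher levels passed without DMSO replicate 2 (median -0.03, adjusted p = 0.0349) and without EPZ replicate 1 (median -0.07, adjusted p = 0.00024), and in no other of these 8.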

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

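The tests in this part were chosen after the results they weigh were seen; for GC content and length alone, what each outcome would mean was written down before the test was run. DOT1L stood out in a comparison outside the report's tests, across tables normalized separately: its mean FPKM in EV was 26.5 times that in DMSO (12.6), and its log2 ratio, with 0.5 added to each value, was 4.68. Only 4 of 13657 genes had a higher ratio (CRIP1, SQLE, PDE4B and CPA4), and 243 genes lay at least 4-fold apart either way. These ratios sum every transcript listed for each group, without the 5% limit on transcripts listed in 1 table. A different scale of the tables does not account for this, since the median log2 ratio over all genes was -0.12. The main coding transcript rose over DMSO at least 10.4 times as much as the transcript with a retained intron in each knockdown line. The latter had low values, at a mean of 0.383 FPKM in DMSO and 0.868 in EV. The coding transcripts did not all rise alike. Another one stood at 0.789 and 0.425 FPKM in DMSO and at 1.85 and 1.04 in EV, while a further one reached 64.6 and 78.1 in EV. The ratio therefore cannot decide whether the lines carry an added coding copy of DOT1L. The labels name no such copy, and no parental line is among the libraries, so with 4 genes above DOT1L a difference between the cells of the 2 experiments cannot be told apart from it.

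Of the 752 transcripts called in the authors' EPZ table, 651 were at 0 in both libraries of a group and 101 were above 0 in both groups. Switching of transcripts by the inhibitor would need more all-or-none transcripts with the right labels than with wrong ones. This was counted over all transcripts, called or not, at 0 in one pair and at a mean of at least 1 FPKM in the other. The labelled split held 545 and the higher mislabelled split 561, a ratio of 0.971. Gene sums of the 651 called transcripts moved by a median of 0.14 on the log2 scale, so reads of a gene assigned to another of its transcripts are a candidate explanation. DMSO replicate 1 stands apart here, with 1550 transcripts at 0 in one DMSO library and at 2 FPKM or more in the other, against 730 between the EPZ libraries. Single transcripts that do respond to EPZ remain possible, since the count says nothing of each one.

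The mean log2 fold change of FOS, FOSB and CCN1 in K56A versus WT was -0.47, and it was -0.50 after trends with GC content and length were removed from each library, with FOS at -0.68 ± 0.04, so such a trend is not the whole cause. The scale of the separate tables is not either, as the EV libraries differ by at most 0.00102 on the log2 scale. A graded effect of DOT1L alone would lower them at least as much from EV to WT, the larger step of DOT1L, yet the log2 fold change there lay above that from WT to K56A by 0.41 ± 0.06 (SE) for FOS and 0.43 ± 0.07 for CCN1, which was 175 ± 0.318 FPKM (SD, n = 2) in EV. For FOSB it lay at -0.0860 ± 0.0726, and DOT1L, 0.32 higher in K56A (0.20 with those trends removed), cannot be told apart from the K56A change there, nor can a DOT1L effect that is not graded or that the change of CDK9 offsets for any of the 3, since no pair of lines had equal DOT1L. The 3 genes were picked for their fall from WT to K56A in these same libraries, and WT enters both steps. That choice pushes the differences upward and their SE leaves it out, so they weigh less against a graded effect than the SE implies. Labels do not say whether the 2 libraries of a line are separate cultures, so a difference between single cultures cannot be told apart from K56A either. A biological effect of K56A thus remains a hypothesis.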

How the results depend on the processing

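The tests of transcripts, of all transcripts of the authors' own table, without the limit on transcripts listed in 1 table, with GC and length trends removed, and of lists without single libraries and at pseudocounts 0.1 and 1 were chosen after the result was seen. Alternatives for counts were not run, since the values are FPKM. Of 839 alternative values of named genes, 546 kept direction and side of the threshold, 259 no longer passed, 31 newly passed and 3 reversed, all of CDK9 in EPZ versus DMSO, which passed in none (0.0436 with GC and length trends removed, -0.126 to 0.0950 leaving out 1 library). Of 220 for lists that passed, 169 still passed, 51 did not and 0 reversed in camera's direction, though the median of immediate early genes in K56A versus EV turned from -0.04 to 0.01 without K56A replicate 2. The cause of the changes below was not tested, apart from fewer genes or libraries where the setting itself removes them. Counts of changed genes are given in the order EPZ versus DMSO (1), WT versus EV (62), K56A versus EV (91) and K56A versus WT (7). Leaving out 1 library gave 34 to 1560, 2 to 7, 6 to 38 and 1 to 2. No filter gave 0, 40, 55 and 1, a mean FPKM of at least 5 gave 0, 168, 180 and 21, and all 10 libraries in 1 fit gave 2, 3, 4 and 0. Transcripts instead of genes gave 0, 8, 8 and 2, of which 0, 2, 1 and 0 were lower. Only the 2 groups compared gave 11, 25 and 21 for the knockdown lines, and the authors' own table gave 10 and 22 for both comparisons with EV. GC and length trends removed gave 0 with EPZ, 104 in WT versus EV and 155 in K56A versus EV, and pseudocount 0.1 gave 0 with EPZ. The replicate number as a block gave 2, 46, 53 and 3, and it is not shown to pair libraries, since deviations with the same number had r = 0.245 for DMSO and EPZ, 0.0332 for EV and WT, -0.0149 for EV and K56A and -0.0334 for WT and K56A. Lists past the threshold (4, 6, 8 and 4) were 0 in each comparison with an estimated correlation and 0 with EPZ and 2 in K56A versus WT with fry. Leaving out 1 library gave 1 list with EPZ at the lowest (without DMSO replicate 2) and 5 in K56A versus EV (without EV replicate 2). The correlation of EPZ and K56A effects was -0.304 with a mean FPKM of at least 5 and -0.267 to -0.0635 leaving out 1 library, and that of WT and K56A effects 0.522 to 0.742. Depth is unknown, so no interval for low genes was given.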

Other observations

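The values in this part were all chosen after they were seen, and no difference between the experiments was tested. Genes other than DOT1L also differed widely between the experiments, which are both labelled HCT116. SQLE, a rate-limiting enzyme of cholesterol synthesis, stood at 0.290 ± 0.126 FPKM (SD, n = 2) in DMSO and 37.4 ± 0.384 in EV. CRIP1, a LIM domain protein gene, stood at 0.753 ± 1.06 and 70.5 ± 2.26, the phosphodiesterase PDE4B at 0.469 ± 0.101 and 42.4 ± 0.192, and the carboxypeptidase CPA4 at 0.282 ± 0.399 and 23.2 ± 0.0736. GH1, growth hormone, was listed at 11.5 ± 0.801 FPKM in EV, 14.4 ± 0.0499 in WT and 15.8 ± 0.0693 in K56A and was not listed in the inhibitor table. These values come from tables normalized separately.

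CD83, a surface protein of activated immune cells, shows how a choice of transcripts moves a value. Summed over transcripts listed in both knockdown tables, it stood at 7.19 and 7.56 FPKM in EV and at 1.28 and 1.52 in WT. Summed over every transcript of the WT table, WT held 6.49 and 6.14. Transcripts listed in 1 table held 77.8% of its FPKM in a group, and CD83 was therefore left out of the tests.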
